A study of Homo sapiens with 12 samples.

How the data were processed

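Total RNA from human plasmacytoid dendritic cells (pDCs) was measured on 12 arrays, 3 at each of 0, 4, 8 and 12 h after the cells were given 0.5 µM CpG-B. Per the labels, the cells came from healthy donors and were isolated with a kit as cells without markers of other lineages, such as CD3 (T cells), CD14 (monocytes), CD19 (B cells), CD56 (NK cells) and CD11c (conventional dendritic cells). The RNA was labelled with biotin and hybridised to Illumina BeadChips of the HumanHT-12 V4 type, on which oligonucleotide probes on beads capture transcripts. All 12 arrays lay on 1 chip, on which the 4 times of replicate 1 came first, then those of replicate 2 and then those of replicate 3, so replicate number and position on the chip go together and no slide separates the times.

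The authors named GenomeStudio in their processing notes, without a version. The deposited probe table holds intensity values that were not scaled between arrays, with a detection p-value beside each. Background subtraction was not stated but was seen in the values: between 28.62% and 32% of the probes on each array were below 0. Per the file headers, the p-value is a detection p-value, and it moves in steps of 1 in 770, as a rank against 770 negative control probes would. A further deposited table, the series matrix, holds the same intensity values times 1 factor per array, between 0.7405 and 1.581, which brings the mean of every array to 105.589. Every column of the tables was matched to a sample, with 0 columns left unmapped. Between arrays, 0% of the values were identical.

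The probe table was read into R 4.3.3 with data.table (version 1.17.8) and analysed with limma 3.58.1. Background was modelled from the detection p-values by normexp with an offset of 16, and the values were put on the log2 scale and quantile normalised. Of 47323 probes, 30113 had 1 gene symbol in the array annotation, 8 were listed with several genes and 17202 were not listed with a gene. The gene IDs of 30074 probes were found in a RefSeq gene table, and 0 symbols were changed by it. No probe positions were given, so no coordinates are reported. Probes of XIST, TSIX and Y-linked genes, 144 in all, were left out. A probe was kept when its detection p-value was below 0.01 on at least 3 arrays, which 12547 named probes met. For each gene the probe with the highest mean over the 12 arrays was used, and 9711 genes were tested. Several detected probes were found for 2324 genes, and probes of 1 gene passed the test in opposite directions for 25, 35 and 27 genes at 4, 8 and 12 h against 0 h. Genes of near-identical sequence, such as those of the IFNA, CCL3 and CCL4 families, the HSPA1 pair and ribosomal proteins, can bind each other's probes, and their values cannot be separated with certainty.

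The 4 times were fitted together with lmFit and eBayes on all 12 arrays, without a term for replicate. Contrasts were 4, 8 and 12 h against 0 h, 8 h against 4 h and 12 h against 8 h, with 12 h against 4 h for gene lists, and an F test asked for any difference between the 4 times. limma's moderated test is two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05. Values are means of normalised log2 intensity with their SD over 3 arrays, and the SE of a log2 fold change is that of the fit. A 3 against 3 permutation test cannot go below 0.1 and was not used for single genes. The labels do not say whether each replicate is a separate donor, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

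Gene lists, the rule for named genes, the comparisons and most alternatives were fixed before the data were examined. The 25 lists cover the MYC network, the IRF family, type I and III interferons, interferon-stimulated genes, TLR9 signalling, NF-kB targets and feedback, inflammatory cytokines and chemokines, maturation and antigen presentation, pDC identity, MYC-activated growth genes, ribosomal proteins, glycolysis, oxidative phosphorylation, cholesterol synthesis, the unfolded protein response and secretion, apoptosis and survival, the cell cycle, immediate early genes, and markers of T cells, B cells, NK cells, monocytes, conventional dendritic cells, basophils and progenitors, and platelets and red cells. Together they hold 523 tested genes, of which 21 stand in more than 1 list. In the pDC identity and NF-kB lists 8 members each, and in the TLR9 list 7, are also in another list, and no member of the lists for other cell types is. Each list was tested against all other genes with camera at a preset correlation between genes of 0.01, and again with the correlation estimated. The rotation test fry, which does not compare a list with other genes, was run on the same lists. The p-values were adjusted over the 25 lists within a comparison. Members past the test were counted over all genes tested and adjusted over the list alone.

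The genes named for each comparison with 0 h were the 8 largest rises and the 8 largest falls with adjusted p below 0.05, whose 3 arrays of one time all lay above the 3 of the other and which were detected on all 3 arrays of the higher time. For 8 h against 4 h and 12 h against 8 h the rule took 5 each way. MYC and IRF7 were always named, and examples from a list were taken from its 4 members with the largest change in a comparison. Genes of the HLA-DR beta and HLA-DQ types, GSTM1, GSTT1 and unnamed gene models were never named. Where no array of the lower time detected a gene, its fold is given as "at least", computed against the detection limit of those arrays. This bound holds for the probe used, and another probe of the gene can give a smaller change. For CCR2 and MS4A6A only the probe used went undetected.

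The alternatives were no background correction, an offset of 50, median scaling, cyclic loess, the series matrix values, no filter on dim probes, detection on all 12 arrays, the mean of a gene's probes, each probe on its own, a replicate block as a fixed or a random term, only the 2 times compared, trend and robust options, array weights, a change of at least 2-fold, and leaving out each array or each replicate. Scaling by the median of the probes detected on all 12 arrays and scaling by ribosomal protein genes were added after seeing the data. Whether replicate numbers pair the arrays was checked from correlations of each array's deviations from its time's mean. Arrays of the same number at different times correlated at a median of 0.16, 0.33 and 0.16 for numbers 1, 2 and 3. Numbers 1 and 3 also correlated with each other at 0.16, while number 2 correlated with each of them at -0.22. Deviations from a mean sum to 0, so a number 2 that stands apart makes numbers 1 and 3 correlate. The best partner had the same number for 9 of the 12 arrays. Results with the block are therefore given for the counts of each comparison, for lists whose call it changed and for some single genes.

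The pipeline was tested on simulated data with 200 changed genes among 11267. It called 65 of 100 genes changed 2-fold and 99 of 100 changed 4-fold in the right direction, 0 in the wrong direction and 13 unchanged genes. The median estimates were 0.86 and 1.66 for true log2 changes of 1 and 2, so changes were underestimated in the simulation. The changed genes were drawn from those detected on all 3 arrays of 0 h, and no replicate effect was simulated. These rates therefore do not cover genes undetected at 0 h, such as MYC and IFNB1. The simulated shift of 1 list of 50 genes was called, and 0 of 24 unshifted lists were. Noise was drawn for each probe on its own, so the simulated genes did not correlate. In the data the estimated correlation was 0.82 for the interferon list, so the simulation does not test calls of correlated lists. As many genes were changed up as down in it, while in the data 51.1% of genes were called at 4 h. How quantile normalisation behaves with that many changes was therefore not tested. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.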

Results

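Plasmacytoid dendritic cells, blood cells that make large amounts of type I interferon when their endosomal toll-like receptors bind nucleic acid, were stimulated with CpG-B, an oligonucleotide with unmethylated CpG motifs that the receptor TLR9 recognises. Expression was measured on 12 arrays at 0, 4, 8 and 12 h, with 3 replicates at each time. The series was set up to ask whether MYC, a transcription factor that drives cell growth, represses IRF7, the transcription factor that drives interferon genes in these cells. No array held cells kept in culture without CpG-B, so every comparison joins the stimulation with the time in culture. Mean intensity ran from 66.79 on the array of 8 h replicate 1 to 142.6 on that of 12 h replicate 2. All 12 h arrays, at 124 to 142.6, were brighter than every other array, of which the highest was 117.7. Between 12277 probes (4 h replicate 3) and 15413 probes (0 h replicate 3) were detected, and the 4 h arrays, with 12277 to 12817, lay below the 0 h arrays, with 13876 to 15413. Arrays of the same time correlated at 0.96 to 0.99 across probes, and arrays of different times at 0.78 to 0.97, where probes are not independent replicates. Between any of the 4 times, 6108 of 9711 genes (62.9%) differed in limma's F test. This count was 3632 without replicate 1, 6272 without replicate 2 and 3561 without replicate 3.

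MYC rose after stimulation while IRF7 fell from a high level. MYC was detected on no array at 0 h (normalised log2 intensity 4.32 ± 0.03, SD, n = 3) and reached 7.63 ± 0.21 at 4 h, 7.70 ± 0.37 at 8 h and 9.11 ± 0.24 at 12 h. On the probe used, these are rises of at least 7.48-fold, 7.87-fold and 20.9-fold (log2 fold changes 3.31, 3.38 and 4.79, SE 0.20, adjusted p = 2.46e-09, 2.11e-09 and 3.98e-11). A second MYC probe, detected on 9 arrays, rose less, with log2 fold changes of 2.11, 2.3 and 3.42. IRF7 stood at 12.86 ± 0.20 at 0 h, 12.72 ± 0.28 at 4 h, 12.13 ± 0.24 at 8 h and 11.79 ± 0.25 at 12 h (SD, n = 3). It fell by 0.73 on the log2 scale at 8 h (1.66-fold, SE 0.20, adjusted p = 0.00745) and by 1.07 at 12 h (2.1-fold, SE 0.20, adjusted p = 0.000419). At 4 h its log2 fold change was -0.14 (adjusted p = 0.59), with values from -0.17 to 0.26 under other scalings. The IRF7 call at 8 h ended without replicate 1 (-0.66, adjusted p = 0.116) and without replicate 3 (-0.77, adjusted p = 0.0501).

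**Figure D1:**
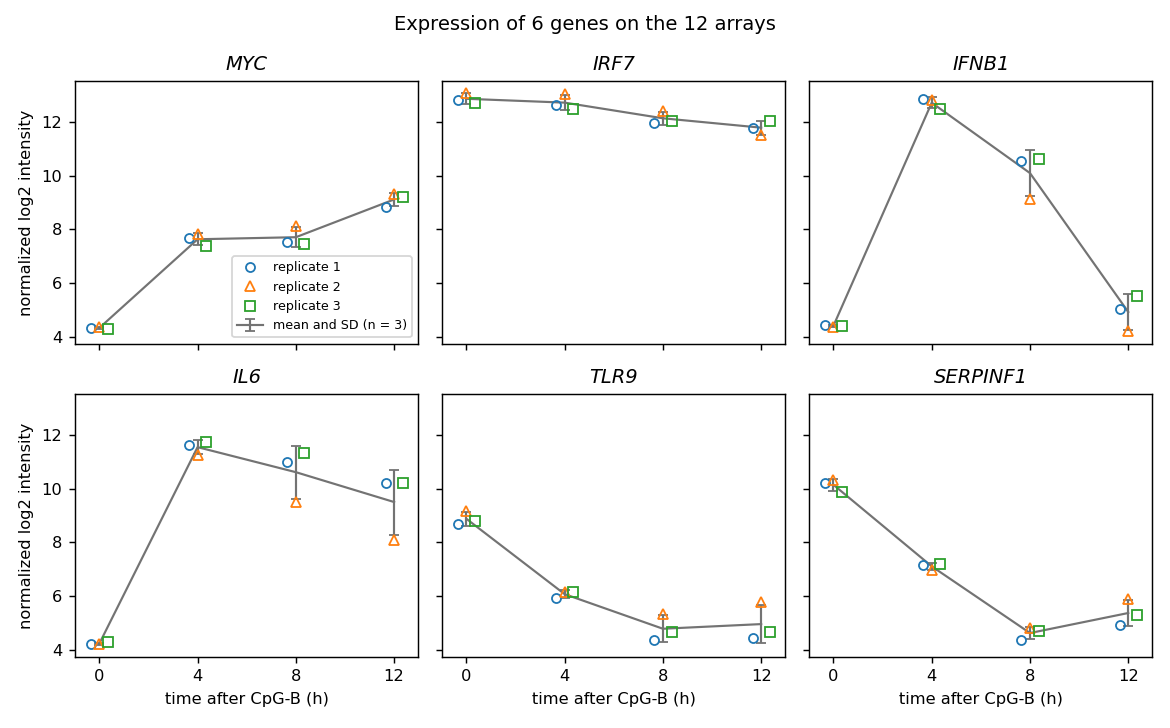
Normalised log2 intensity of MYC, IRF7, IFNB1, IL6, TLR9 and SERPINF1 against time after CpG-B in hours, with 1 symbol per array and lines through the mean with SD bars (n = 3). MYC rose from 4.32 to 9.11 and IRF7 fell from 12.86 to 11.79 between 0 and 12 h, while IFNB1 reached 12.72 at 4 h and stood at 4.92 at 12 h.

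At 4 h against 0 h, the comparison of the early response, the largest rises of the genes named were those of interferon and chemokine genes. IFNB1, a type I interferon, went from 4.40 ± 0.04 to 12.72 ± 0.21 (SD, n = 3), at least 255-fold higher (log2 fold change 8.32, SE 0.35, adjusted p = 3.77e-11). IFNA14, IFNA16 and IFNA7, other type I interferons, were at least 253-fold, 232-fold and 238-fold higher on the probes used. Second probes of IFNA14 and IFNA7 gave log2 fold changes of 7.18 and 6.81. The chemokine genes CCL3L1, CCL3L3, CCL3 and CCL4L1, whose products attract immune cells, rose 317-fold, 300-fold, 275-fold and 259-fold. A second CCL4L1 probe, detected on 3 arrays, had a log2 fold change of 2.53. The largest falls were those of PAFAH2, a phospholipase that acts on oxidised lipids, by 4.70 on the log2 scale (26-fold, SE 0.32, adjusted p = 9.58e-09), of the tyrosine phosphatase PTPRE, 22.7-fold, and of TGFBR2, a receptor for TGF-beta, 20.2-fold. CCR2, a chemokine receptor, fell at least 16.6-fold on the probe used, which no 4 h array detected although another CCR2 probe was detected there. MBP fell 18.5-fold, the semaphorin receptor gene PLXNB2 16.9-fold, PACSIN1 16.3-fold and IRF2BPL at least 12.4-fold.

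All 18 interferons tested rose at 4 h, adjusted over the list alone as well as over all genes, with a median log2 fold change of 6.60, or 6.16 with undetected genes at their bounds (camera adjusted p = 1.1e-17). With an estimated correlation the adjusted p for that list was 0.134. Of 47 interferon-stimulated genes, 44 rose and 0 fell (44 and 0 adjusted over the list alone; median 1.85, adjusted p = 5.79e-21, and adjusted p = 0.0885 with an estimated correlation). Examples are the chemokine gene CXCL10 (39.1-fold), OASL (32.4-fold) and IFIT2 (14.3-fold). Of 29 NF-kB targets, 24 rose and 0 fell (25 and 0 adjusted over the list alone; median 1.75, adjusted p = 4.62e-14), among them TRAF1 (22.3-fold), the survival gene BCL2L1 (22-fold), the NF-kB subunit REL (19-fold) and TNF (18.3-fold). Of 28 inflammatory cytokines and chemokines, 23 rose and 0 fell (24 and 1 adjusted over the list alone; median 3.90, adjusted p = 2.36e-17), with IL6 at least 113-fold higher. Of 42 genes of maturation and antigen presentation, 29 rose and 1 fell (31 and 1 adjusted over the list alone; median 1.08, adjusted p = 4.14e-10, and adjusted p = 0.0586 with an estimated correlation). The costimulatory receptor gene CD40 rose 47.9-fold, the maturation marker CD83 24.4-fold and CD70 at least 22.7-fold. Of 19 genes of apoptosis and survival, 12 rose and 3 fell, the same adjusted over the list alone (median 0.86, adjusted p = 3.38e-06). Risers included the survival kinases PIM2 (32-fold) and PIM1 (at least 25-fold) and also BCL2L11 (at least 17.5-fold), which promotes cell death.

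Among 39 genes of pDC identity, 30 fell and 2 rose at 4 h, the same adjusted over the list alone (median -1.31, adjusted p = 9.26e-08). SCAMP5 fell 11.9-fold, the transcription factor RUNX2 9.69-fold and the secreted factor SERPINF1 8.22-fold. TLR9 itself fell 7.01-fold, from 8.88 ± 0.25 to 6.07 ± 0.13 (SD, n = 3), though its pathway list was not called by camera (4 rose and 10 fell of 24; median -0.34, adjusted p = 0.398). The calls for NF-kB targets, cytokines, apoptosis genes and pDC identity held with an estimated correlation (adjusted p = 0.0329, 0.0373, 0.0265 and 0.0265). Of 21 immediate early genes, 10 rose and 4 fell (the same adjusted over the list alone; median 0.03, mean 0.98, adjusted p = 0.0473, and adjusted p = 0.664 with an estimated correlation), with JUN at least 20.2-fold and NR4A3 13-fold higher. That call ended without 4 h replicate 1 (adjusted p = 0.0572) and without 0 h replicate 2 (adjusted p = 0.0896), and also with an offset of 50, detection on all 12 arrays and the mean of probes (adjusted p from 0.0654 to 0.0664).

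Genes of MYC's own network went both ways at 4 h, 4 up and 4 down of 12 (median -0.07, adjusted p = 0.915), with the MYC antagonist MXD4 down 12-fold and the MYC partner ZBTB17 up 2.23-fold. In the IRF family 3 rose and 3 fell of 8 (median -0.22, adjusted p = 0.915), and IRF3 fell 2.61-fold and IRF5 2.11-fold. Of 51 MYC-activated growth genes, 16 rose and 7 fell (median 0.02, adjusted p = 0.189), with NOLC1, a nucleolar protein gene, up 4.34-fold and PHB1, a mitochondrial protein gene, down 4.13-fold. In glycolysis 4 rose and 6 fell of 21 (adjusted p = 0.827), with the glucose transporter gene SLC2A1 down 16-fold and the glycolysis regulator PFKFB3 up 3.91-fold. Of 42 genes of oxidative phosphorylation, 18 fell and 3 rose (median -0.40, adjusted p = 0.0804).

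limma's test called 4959 genes at 4 h (51.1%), 2034 higher and 2925 lower, and 5363 with replicate as a block. Of these 4959, 2176 changed at least 2-fold, and the arrays of the 2 times did not overlap for 57.5% of genes, where chance gives 10%. The count was 3157 without replicate 1 and 3053 without replicate 3. The highest count with arrays left out was 5100, without 12 h replicate 2. Higher genes made up 41% of those called, against 25.8% with median scaling, 26.3% with the series matrix values, and 50.1% and 24.3% with the scalings by probes detected on all 12 arrays and by ribosomal protein genes, which were added after seeing the data.

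**Figure D2:**
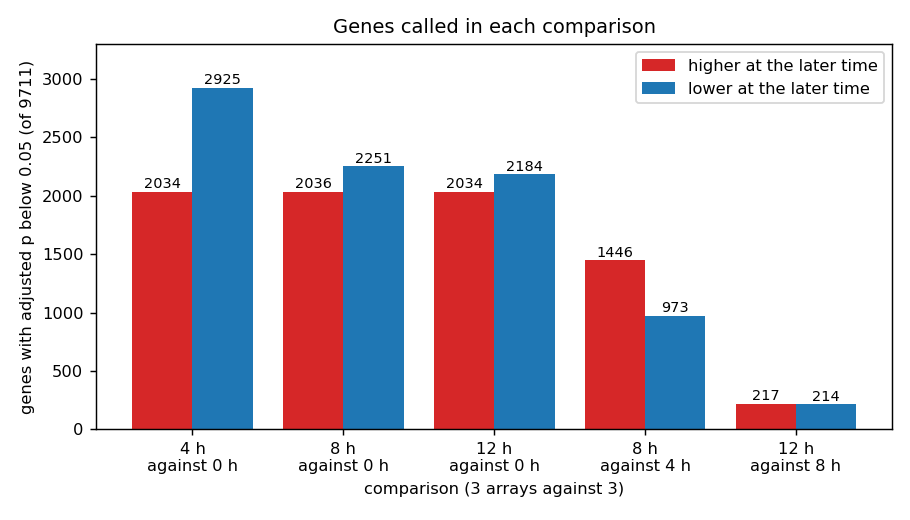
Number of genes with adjusted p below 0.05, of 9711 tested, for 5 comparisons of 3 arrays against 3; red bars count genes higher and blue bars genes lower at the later time. The bars run from 2925 genes lower at 4 h against 0 h to 214 genes lower at 12 h against 8 h.

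At 8 h against 0 h, which asks what the cells expressed midway, interferons were still raised and genes typical of pDCs had fallen deeply. IFNA14 was at least 63.2-fold, IFNA7 at least 55.5-fold, IFNA16 at least 48.6-fold and IFNB1 at least 41.4-fold higher than at 0 h on the probes used. Second probes of IFNA14 and IFNA7, each detected on 6 arrays, gave log2 fold changes of 3.64 and 4.46. IL6 was at least 59.3-fold higher, and IL36G, a cytokine of the IL-1 family, went from 4.30 ± 0.06 to 10.64 ± 0.20 (SD, n = 3), at least 60.3-fold higher (log2 fold change 6.33, SE 0.18, adjusted p = 8.03e-13). CCL3L3 and CCL4L1 were 71.1-fold and 70.4-fold higher, while a second CCL4L1 probe, detected on 3 arrays, had a log2 fold change of -0.09. The largest fall was that of LRRC26, a gene marking pDCs, from 10.82 ± 0.12 to 5.08 ± 0.23 (53.6-fold, SE 0.20 for a log2 fold change of -5.74, adjusted p = 6.74e-12). SERPINF1 fell 46-fold, PACSIN1 45.7-fold, the tyrosine kinase gene FES 34.8-fold, the tropomyosin gene TPM2 33.7-fold, CYTH4 29.9-fold, SEPTIN9 27.2-fold and the adaptor gene LIME1 26.8-fold.

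Of 39 pDC identity genes, 36 fell and 1, the transcriptional regulator ID2, rose at 8 h, the same adjusted over the list alone (median -2.02, or -1.97 with bounds, adjusted p = 2.38e-17, and adjusted p = 0.00169 with an estimated correlation). TLR9 fell 17.1-fold. Of 18 interferons, 16 rose and 0 fell, the same adjusted over the list alone (median 4.04, or 3.54 with bounds, adjusted p = 4.79e-11, and adjusted p = 0.317 with an estimated correlation). Of 47 interferon-stimulated genes, 46 rose, the same adjusted over the list alone (median 1.79, adjusted p = 1.01e-21), with CXCL10 up 29-fold and the antiviral gene RSAD2 up 17.6-fold. Of 29 NF-kB targets, 18 rose and 2 fell (18 and 3 adjusted over the list alone; median 1.2, adjusted p = 2.97e-06), with BCL2L1 up 18.5-fold and SOD2 up 10.6-fold. Of 28 cytokines and chemokines, 18 rose and 1 fell, the same adjusted over the list alone (median 2.45, adjusted p = 5.24e-09), and of 42 maturation genes, 26 rose and 1 fell (27 and 1 adjusted over the list alone; median 0.84, adjusted p = 3.7e-07), with CD80 up 19.1-fold and CD86 up 13.4-fold. For these 4 lists the adjusted p was 0.143 with an estimated correlation. Of 51 MYC-activated growth genes, 24 rose and 2 fell (25 and 2 adjusted over the list alone; median 0.53, adjusted p = 5.62e-05, and adjusted p = 0.466 with an estimated correlation), with NOLC1 up 3.95-fold and MRTO4, which acts in ribosome assembly, up 2.75-fold. Of 19 apoptosis and survival genes, 10 rose and 0 fell, the same adjusted over the list alone (median 0.78, adjusted p = 5.99e-05, and adjusted p = 0.0581 with an estimated correlation), with PIM2 up 9.23-fold and BCL2 up 8.4-fold.

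limma's test called 4287 genes at 8 h (44.1%), 2036 higher and 2251 lower, and 4781 with replicate as a block. Of these 4287, 1858 changed at least 2-fold. The count was 2548 without replicate 1 and 2540 without replicate 3, and the highest with arrays left out was 4434, without 12 h replicate 2. The share of higher genes, 47.5%, was 26.2% with median scaling.

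At 12 h against 0 h, the latest time, no interferon gene passed the test, while CCL3L3, CCL4L1, CCL3, CCL3L1 and IL6 were still higher than before stimulation. IFNB1 stood at 4.92 ± 0.66 against 4.40 ± 0.04 (SD, n = 3; log2 fold change 0.52, SE 0.35, adjusted p = 0.25), and 0 of 18 interferons passed limma's test (0 at unadjusted p below 0.05; median 0.07, adjusted p = 0.615). Without replicate 2, the log2 fold changes of IFNB1 (0.81, adjusted p = 0.00135), IFNA14 (0.98, 0.000154), IFNA16 (0.77, 0.00116) and IFNA7 (0.61, 0.00862) passed. IFNA14, at 0.71 (adjusted p = 0.186) with every array, also passed with replicate as a block (adjusted p = 0.0299). CCL3L3 was 53.9-fold, CCL4L1 53.8-fold, CCL3 36.4-fold and CCL3L1 31-fold higher, and IL6 at least 27.4-fold. The second CCL4L1 probe, detected on 3 arrays, had a log2 fold change of -0.01. EBI3, a subunit of the cytokines IL-27 and IL-35, rose 36.1-fold, CKB, a creatine kinase gene, 36.2-fold and ARHGAP22 at least 26.4-fold. LRRC26 fell by 5.93 on the log2 scale, from 10.82 ± 0.12 to 4.89 ± 0.41 (61.1-fold, SE 0.20, adjusted p = 6.07e-12), the ribonuclease gene RNASE6 42-fold, TPM2 38.1-fold, PACSIN1 29.7-fold, SERPINF1 27.5-fold and JAML, an adhesion molecule gene, 23.1-fold. CCR2 fell at least 18.3-fold, and MS4A6A at least 26.4-fold on the probe used, which no 12 h array detected although another probe of the gene was detected there.

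Of 39 pDC identity genes, 34 fell and 1, ID2, rose at 12 h (35 and 1 adjusted over the list alone; median -2.15, or -2.07 with bounds, adjusted p = 9.18e-18, and adjusted p = 0.00145 with an estimated correlation). The rotation test fry gave the same direction for this list (adjusted p = 1.44e-08). With fry, interferons at 4 h (adjusted p = 6.67e-06) and interferon-stimulated genes at 12 h (adjusted p = 6.04e-05) were called higher too. Some lists that camera did not call were called by fry, which does not compare a list with other genes. Among them were TLR9 signalling at 4 h (lower, adjusted p = 0.000326) and the MYC network at 12 h (higher, adjusted p = 0.000331). In the TLR9 list 11 fell and 3 rose of 24, the same adjusted over the list alone (median -0.41, adjusted p = 0.0418), with TLR9 down 15.2-fold, CLEC4C, which encodes the pDC surface lectin BDCA-2, down 7.05-fold and LILRA4 down 4.75-fold. TLR9, CLEC4C and LILRA4 are also in the pDC identity list, as are all 7 members that the TLR9 list shares with another list. The call for the TLR9 list is thus not independent of the fall of identity genes. It had adjusted p = 0.183 with an estimated correlation and ended without 12 h replicate 2 (adjusted p = 0.0578). It also ended in 5 of 15 other settings, with median scaling, the series matrix values, detection on all 12 arrays and both added scalings (adjusted p from 0.0522 to 0.17). Of 47 interferon-stimulated genes, 43 rose and 0 fell (46 and 0 adjusted over the list alone; median 1.45, adjusted p = 2.62e-17), with CXCL10 up 14.2-fold and IFI27 up 12.1-fold. Of 29 NF-kB targets, 18 rose and 1 fell, the same adjusted over the list alone (median 1.12, adjusted p = 2.28e-06). Of 28 cytokines and chemokines, 18 rose and 2 fell (18 and 3 adjusted over the list alone; median 1.87, adjusted p = 1.27e-07). Of 42 maturation genes, 23 rose and 5 fell, the same adjusted over the list alone (median 0.68, adjusted p = 1.33e-05), with CD80 up 16.2-fold and the actin-bundling gene FSCN1 18.8-fold. With an estimated correlation the adjusted p was 0.183 for these 4 lists too, and the cytokine call ended with detection on all 12 arrays (adjusted p = 0.0516).

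Of 51 MYC-activated growth genes, 33 rose and 2 fell at 12 h (35 and 2 adjusted over the list alone; median 0.74, adjusted p = 1.59e-08, and adjusted p = 0.212 with an estimated correlation). NOLC1 rose 4.69-fold, NOP16 3.86-fold and ODC1, the first enzyme of polyamine synthesis, 3.14-fold. In the MYC network 3 rose and 2 fell of 12 (median -0.08, mean 0.28, adjusted p = 0.615), with MXD4 down 5.62-fold and ZBTB17 up 2.75-fold. In the IRF family 2 rose and 3 fell of 8 (median -0.34, adjusted p = 0.593), with IRF8 down 2.09-fold, IRF3 down 2-fold and IRF2 up 2.04-fold. Of 19 apoptosis and survival genes, 10 rose and 0 fell, the same adjusted over the list alone (median 0.73, adjusted p = 2.09e-05, and adjusted p = 0.0419 with an estimated correlation), with BCL2 up 8.45-fold and PIM2 7.18-fold. In cholesterol synthesis 8 rose and 1 fell of 19 (9 and 1 adjusted over the list alone; median 0.45, adjusted p = 0.0467, adjusted p = 0.623 with an estimated correlation and adjusted p = 0.0515 with the block), a call that ended without replicate 2 or without replicate 3, and without the 0 h or 12 h array of either (adjusted p from 0.052 to 0.23). It ended in 6 of 15 other settings, with no background correction, cyclic loess, detection on all 12 arrays, the fixed or random block and array weights (adjusted p from 0.0515 to 0.163).

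The other pathway lists were not called by camera at 12 h. Of 48 ribosomal protein genes, 6 rose and 1 fell (median 0.04, adjusted p = 0.219), of 21 glycolysis genes 8 rose and 4 fell (median 0.35, adjusted p = 0.216), and of 42 oxidative phosphorylation genes 5 rose and 3 fell (median -0.04, adjusted p = 0.823). In the unfolded protein response 8 rose and 5 fell of 25 (median 0.36, adjusted p = 0.593), with the stress factor gene ATF3 up 5.65-fold and the chaperone gene DNAJB9 down 3.67-fold. Of 13 cell cycle genes, 1 rose and 1 fell (median -0.01, adjusted p = 0.968). Of 21 immediate early genes, 9 rose and 4 fell (median 0.42, adjusted p = 0.121, and adjusted p = 0.0313 with replicate as a block).

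limma's test called 4218 genes at 12 h (43.4%), 2034 higher and 2184 lower, and 4738 with replicate as a block. Of these 4218, 1834 changed at least 2-fold. The count was 2432 without replicate 1, 4276 without replicate 2 and 2482 without replicate 3. The share of higher genes, 48.2%, was 63.0% with median scaling and 27.5% with the added scaling by ribosomal protein genes.

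**Figure D3:**
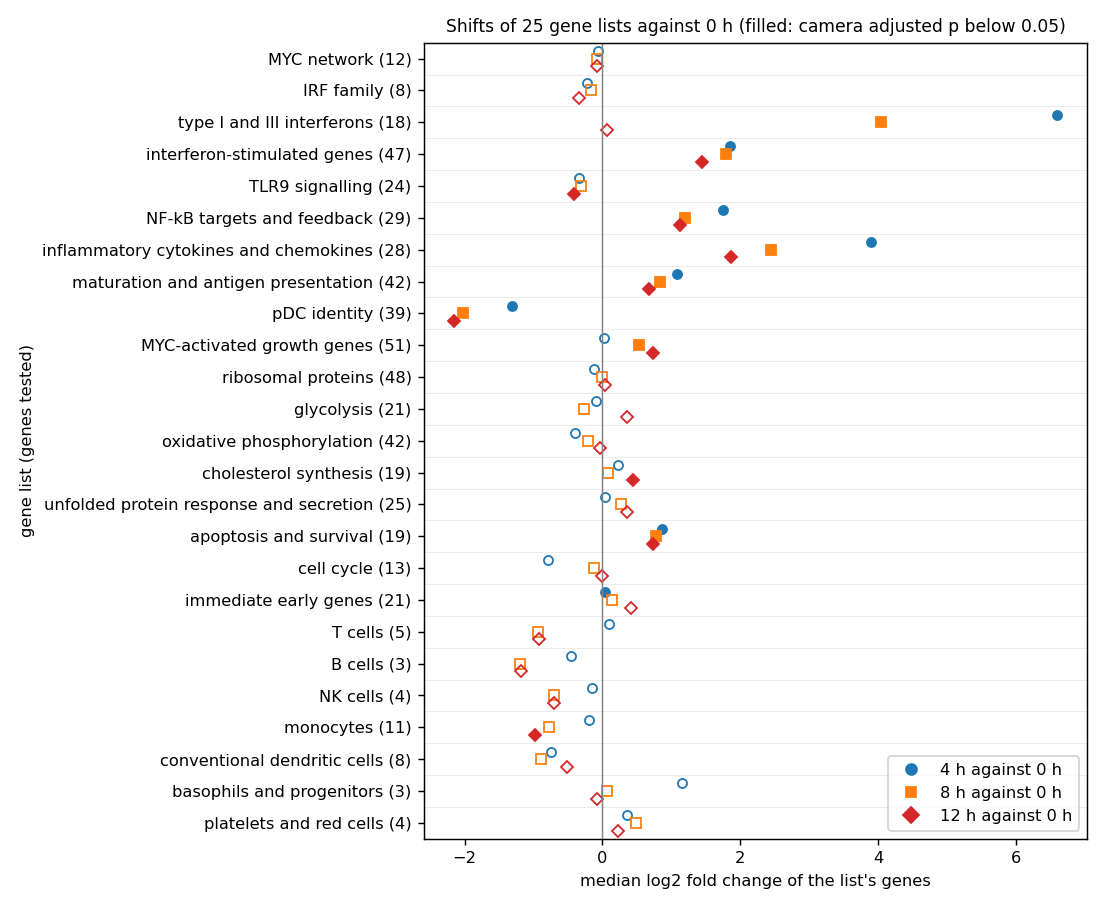
Median log2 fold change of 25 gene lists at 4, 8 and 12 h against 0 h, with the number of genes tested in brackets; filled symbols mark camera adjusted p below 0.05 at a preset correlation. The interferon list went from 6.60 at 4 h to 0.07 at 12 h, and the pDC identity list lay at -1.31, -2.02 and -2.15.

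Markers of other cell types were few among the tested genes, and camera called none of these 7 lists higher in the comparisons with 0 h or in 12 h against 4 h. The monocyte list was lower at 12 h (1 rose and 6 fell of 11; median -0.98, or -0.64 with bounds, adjusted p = 0.0418, adjusted p = 0.58 with an estimated correlation and adjusted p = 0.00365 with replicate as a block), with CSF1R at least 8.37-fold lower. That call ended without replicate 1 (adjusted p = 0.0769), replicate 3 (0.0553), 0 h replicate 1 (0.0972), 0 h replicate 3 (0.0783) or 12 h replicate 2 (0.114), and with no background correction or no filter on dim probes (adjusted p from 0.0515 to 0.0562). At 8 h it had adjusted p = 0.103, and adjusted p = 0.0204 with replicate as a block. Replicate 2 stood apart in this list, with a mean log2 intensity at 0 h of 5.16 against 6.56 and 6.44 in replicates 1 and 3, and LYZ, a lysozyme gene abundant in monocytes, at 7.64 against 9.85 and 9.79. Over the pDC identity list the 0 h values were 8.99, 8.86 and 8.87. Replicate as a block also added calls of single monocyte genes. LYZ (-2.22) and S100A8 (-1.09) then passed at 12 h against 4 h (adjusted p = 1.41e-08 and 0.00792, against 0.0524 and 0.217 without it). CD14 passed at 8 h against 0 h (-1.52, adjusted p = 0.00118, against 0.0784). AQP9 passed as higher at 4 h against 0 h (0.71, adjusted p = 0.0106, against 0.14). For T cells 1 rose and 3 fell of 5 at 12 h (median -0.92, adjusted p = 0.521), for B cells 2 fell of 3 (median -1.18, adjusted p = 0.216) and for NK cells 2 fell of 4 (median -0.70, adjusted p = 0.216). For conventional dendritic cells 3 rose and 4 fell of 8 (median -0.51, adjusted p = 0.615), with CADM1 at least 8.24-fold higher and CX3CR1 at least 10.5-fold lower. For basophils and progenitors 1 fell of 3 (median -0.08, adjusted p = 0.594), and for platelets and red cells 1 rose of 4 (median 0.22, adjusted p = 0.594).

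At 8 h against 4 h, which asks what changed between the early and middle times, IL1B fell the most of all genes named and CADM1 was among those that rose. IL1B, an inflammatory cytokine, fell from 11.28 ± 0.31 to 5.78 ± 0.53 (SD, n = 3; 45.2-fold, SE 0.30 for a log2 fold change of -5.50, adjusted p = 6.19e-09). PTGS2, the inducible cyclooxygenase, fell 13.5-fold, PFKFB3 12.1-fold, LRRC26 15-fold and TPM2 11.7-fold. A second PFKFB3 probe, detected on all 12 arrays, had a log2 fold change of -1.66 against -3.6 on the probe used. For PTGS2 a second probe fell more (-4.34 against -3.75). CADM1, an adhesion molecule gene, rose at least 4.59-fold, the integrin gene ITGA1 5.31-fold, PAM, an enzyme that amidates peptides, 5.14-fold and the lipid droplet gene PLIN2 4.72-fold. A second PLIN2 probe, detected on 9 arrays, had a log2 fold change of 1.17 against 2.24 on the probe used. TUBB2B, a tubulin gene, was at least 3.57-fold higher, a call that ended without replicate 1 (log2 fold change 1.88, adjusted p = 0.0582). MYC did not differ detectably (0.07, adjusted p = 0.828).

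IRF7 differed by -0.59 between 8 and 4 h (1.5-fold, SE 0.20, adjusted p = 0.0419), a call that ended in 8 of 15 fits with arrays left out. The values were -0.55 (adjusted p = 0.262) without replicate 1 and -0.65 (0.146) without replicate 3. They were -0.43 (0.156) without 4 h replicate 2, -0.63 (0.0707) without 4 h replicate 1, -0.50 (0.138) without 8 h replicate 1, -0.53 (0.122) without 8 h replicate 3, -0.58 (0.0535) without 0 h replicate 1 and -0.59 (0.0526) without 12 h replicate 1. It also ended without the filter on dim probes (adjusted p = 0.0715) and with only the 2 times compared (adjusted p = 0.0551). limma's test called 2419 genes between 8 and 4 h, 1446 higher and 973 lower, and 3056 with replicate as a block, of which 833 without the block changed at least 2-fold. The count was 916 without replicate 1, 2973 without replicate 2, 928 without replicate 3 and 1404 with median scaling. The share of higher genes, 59.8%, was 77.1% with the series matrix values, 41.9% at 2-fold or more, and 46.4% and 83.4% with the added scalings by probes detected on all 12 arrays and by ribosomal protein genes.

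At 12 h against 8 h, which asks what changed late, several interferon genes fell and MYC rose again. IFNA14 fell from 10.71 ± 1.16 to 4.96 ± 0.57 (SD, n = 3; 53.8-fold, SE 0.42 for a log2 fold change of -5.75, adjusted p = 5.45e-07), IFNA7 50-fold, IFNA16 46.7-fold, IFNA10 38.2-fold and IFNA13 at least 32.3-fold. MYC was 2.66-fold higher (log2 fold change 1.41, SE 0.20, adjusted p = 0.000802), a call that ended without replicate 1 (1.46, adjusted p = 0.079) and without replicate 3 (1.23, adjusted p = 0.126). YBX3, which encodes a protein that binds DNA and RNA, rose 4.39-fold (log2 fold change 2.13, SE 0.21, adjusted p = 2.05e-05). The chemokine gene CCL22 rose 7.42-fold and SEPTIN9 3.63-fold, calls that ended without replicate 3 (2.66, adjusted p = 0.107, and 1.90, adjusted p = 0.142), and for SEPTIN9 also without replicate 1 (1.76, adjusted p = 0.143). ABHD6, a lipid hydrolase gene, rose 3.98-fold and ID3 3.86-fold (adjusted p = 0.00756 and 0.0162). The ABHD6 call ended without replicate 1 (1.77, adjusted p = 0.207), replicate 3 (2.08, 0.17), 8 h replicate 1 (1.64, 0.0573) or 8 h replicate 3 (1.84, 0.054), and in 2 of 15 other settings (adjusted p from 0.0518 to 0.0669). The ID3 call ended without replicate 1 (1.94, adjusted p = 0.245), replicate 3 (1.76, 0.28), 8 h replicate 1 (1.72, 0.101), 8 h replicate 3 (1.66, 0.106) or 12 h replicate 2 (1.62, 0.053), and in 3 of 14 other settings (adjusted p from 0.05 to 0.111). IRF7 differed by -0.35 (adjusted p = 0.418), with values from -0.42 to 0.28 under other scalings.

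limma's test called 431 genes between 12 and 8 h (4.44%), 217 higher and 214 lower, and 780 with replicate as a block. Of these 431, 191 changed at least 2-fold. The count was 19 without replicate 1 and 15 without replicate 3, and 910 without replicate 2. Leaving out the 8 h array gave 156 for replicate 1 and 150 for replicate 3, and leaving out the 12 h array gave 274 and 281. It was 1944 with median scaling, 660 and 1427 with the 2 added scalings, 253 without the filter on dim probes, 209 with only the 2 times compared and 730 with array weights. The share of higher genes, 50.3%, was 97.2% with median scaling, 28.0% with the added scaling by probes detected on all 12 arrays and 10% with that by ribosomal protein genes. Mean intensity was 124 to 142.6 on the 12 h arrays and 66.79 to 108.4 on the 8 h arrays, so brightness went with time here.

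Gene lists were also compared directly at 12 h against 4 h. All 18 interferons fell, adjusted over the list alone as well (median -6.51, or -6.08 with bounds, adjusted p = 2.86e-25), with IFNB1 down 223-fold. Of 29 NF-kB targets, 19 fell and 1 rose (20 and 1 adjusted over the list alone; median -0.76, adjusted p = 1.92e-09), with REL down 8.74-fold and TNF 6.02-fold. Of 28 cytokines and chemokines, 19 fell and 3 rose (20 and 3 adjusted over the list alone; median -1.94, adjusted p = 9.01e-11), with IL1B down 50.2-fold, LTB, a gene of the TNF family, 15.6-fold and IL12A at least 9.94-fold. For these 3 lists the adjusted p was 0.122 with an estimated correlation. Of 42 maturation genes, 13 fell and 1 rose, the same adjusted over the list alone (median -0.34, adjusted p = 0.00127, and adjusted p = 0.311 with an estimated correlation), with CD40 down 6.26-fold. Of 19 apoptosis and survival genes, 7 fell and 4 rose, the same adjusted over the list alone (median -0.27, adjusted p = 0.00848, and adjusted p = 0.13 with an estimated correlation), with PIM1 down 13.2-fold. The median of that list lay between -0.48 and 0.15 under other scalings, where the test stayed lower, and its call ended with detection on all 12 arrays (adjusted p = 0.0904). Of 47 interferon-stimulated genes, 12 fell and 3 rose, the same adjusted over the list alone (median -0.31, adjusted p = 0.000983, and adjusted p = 0.434 with an estimated correlation), with GBP2 down 4.66-fold. That call ended without replicate 2 (-0.09, adjusted p = 0.0789) and without 12 h replicate 2 (-0.12, adjusted p = 0.0855).

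Of 51 MYC-activated growth genes, 30 rose and 1 fell from 4 to 12 h, the same adjusted over the list alone (median 0.67, adjusted p = 6.85e-06, and adjusted p = 0.315 with an estimated correlation). ODC1 rose 5.02-fold, the cell cycle kinase CDK4 3.35-fold and SRM, an enzyme of polyamine synthesis, 2.72-fold. MYC rose 2.8-fold (log2 fold change 1.48, SE 0.20, adjusted p = 3.92e-05), and IRF7 fell 1.91-fold (-0.93, SE 0.20, adjusted p = 0.00194). In glycolysis 13 rose and 1 fell of 21 (13 and 2 adjusted over the list alone; median 0.73, adjusted p = 0.0106, and adjusted p = 0.311 with an estimated correlation), with the enolase gene ENO1 up 2.88-fold and SLC2A1 3.75-fold, while PFKFB3 fell 8.08-fold. A second PFKFB3 probe had a log2 fold change of -1.81 against -3.01 on the probe used. In oxidative phosphorylation 11 rose and 0 fell of 42 (9 and 0 adjusted over the list alone; median 0.31, adjusted p = 0.0171, and adjusted p = 0.388 with an estimated correlation), with CYC1 up 1.88-fold. Of 13 cell cycle genes, 8 rose and 1 fell, the same adjusted over the list alone (median 0.62, or 0.21 with bounds, adjusted p = 0.0349, and adjusted p = 0.315 with an estimated correlation), with the replication gene MCM6 up 4.26-fold. Without replicate 2 the calls for glycolysis, oxidative phosphorylation and the cell cycle ended (adjusted p = 0.0577, 0.0978 and 0.0724), and that for oxidative phosphorylation also without 12 h replicate 2 (adjusted p = 0.0603). The call for oxidative phosphorylation ended in 3 of 15 other settings as well, with cyclic loess, the series matrix values and the added scaling by detected probes (adjusted p from 0.0591 to 0.0839). The call for the cell cycle ended in 7 of 15, with median scaling, the series matrix values, no filter on dim probes, detection on all 12 arrays, the mean of probes and both added scalings (adjusted p from 0.0503 to 0.153).

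Of 39 pDC identity genes, 22 fell and 4 rose from 4 to 12 h (25 and 4 adjusted over the list alone; median -0.88, adjusted p = 4.61e-08, and adjusted p = 0.0276 with an estimated correlation), with LRRC26 down 17.1-fold, CD4 6.73-fold and CUX2 5.35-fold, while ID3, an inhibitor of DNA-binding factors, rose 5.47-fold. The monocyte list was lower (2 fell and 0 rose of 11; median -0.89, or -0.57 with bounds, adjusted p = 0.0174, adjusted p = 0.358 with an estimated correlation and adjusted p = 0.00153 with replicate as a block), a call that ended without replicate 1 (adjusted p = 0.0534), without 12 h replicate 2 (adjusted p = 0.0624) and with the added scaling by detected probes (adjusted p = 0.0529). In the list of basophils and progenitors 2 fell of 3 (median -1.08, adjusted p = 0.0488, and adjusted p = 0.235 with an estimated correlation), a call that ended without 12 h replicate 1, 12 h replicate 3 or 8 h replicate 3 (adjusted p from 0.0502 to 0.0694). It also ended in 6 of 14 other settings, with no background correction, an offset of 50, cyclic loess, no filter on dim probes, the mean of probes and only the 2 times compared (adjusted p from 0.0566 to 0.147). Of 48 ribosomal protein genes, 8 rose and 1 fell, the same adjusted over the list alone (median 0.20, adjusted p = 0.0488, and adjusted p = 0.388 with an estimated correlation). That call ended in 8 of 15 fits with arrays left out (adjusted p from 0.0507 to 0.163), among them those without replicate 1 and without replicate 2, and in 9 of 14 other settings that do not centre these genes (adjusted p from 0.0545 to 0.858). Among these were the block (adjusted p = 0.0621) and 5 scalings, under which the median ran from -0.21 to 0.43. For conventional dendritic cells the median was -0.33 and the mean 0.21 (adjusted p = 0.72).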

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

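The tests of the 3 patterns below were chosen after the results were seen, and those of other splits of the arrays before. Probes that the array annotation lists with no gene took no part in the comparisons. Among 17202 of them, 126 (0.732%) were detected on no 0 h array but on all 3 arrays of a later time: 73 at 4 h, 50 at 8 h and 55 at 12 h. The reverse, detection on all 3 arrays of 0 h and on none later, held for 76. Among 29969 probes with a gene, 406 (1.35%) went from none to all 3. The genes these 126 probes measure are not known from the tables at hand.

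Genes of pDC identity were lower at 12 h than at 0 h, 34 of 39. A lower share of pDCs among the cells would raise the markers of other cell types if these kept their level per cell. Of 7 lists of such markers, 1 had a median above 0, and 18 of their 38 genes fell and 6 rose. This cannot decide the question, since all cells shared the culture with CpG-B and the level of a marker per cell was not measured. The lists are short, and that of monocytes, called lower, had adjusted p = 0.58 with an estimated correlation and lost its call in 5 of 15 fits with arrays left out, all without a term for replicate, while with replicate as a block it had adjusted p = 0.00365 and its mean fell in 3 of 3 replicates. Normalisation between arrays is argued against, since the median closest to 0 under 6 other scalings was -1.91. Time in culture apart from CpG-B cannot be told apart from stimulation, as 0 arrays held cells cultured without it. A programme of activation in which pDCs lose identity transcripts may account for the fall, and it stays untested.

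More genes were lower than higher at 4 h against 0 h, 2925 against 2034. A few bright probes taking more of the signal at 4 h is argued against, since the share of the 100 brightest probes differed by 0.687 percentage points. Normalisation stays open, since the share of higher genes, 41%, differed between scalings without a common direction: it was 25.8% with median scaling, 26.3% with the series matrix values, 24.3% with ribosomal scaling and 50.1% with the scaling by probes detected on all 12 arrays. Dimmer arrays at 4 h stay open: among the brighter genes 46.2% of those called were higher, closer to an even split than the 41% over all genes but still below it. Fewer probes were detected at 4 h, but mean intensities at 4 h, 82.78 to 117.7, spanned those at 0 h, 97.82 to 107.3.

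IRF7 was lower at 12 h than at 0 h by a log2 fold change of -1.07. Normalisation is argued against, as the value closest to 0 under 6 other scalings was -0.79, and so is a single misleading probe, as another IRF7 probe detected on all 12 arrays gave -1.34. Time in culture was not separable from CpG-B. These tests measure the fall and not its cause: whether MYC brought it about cannot be read from them, since no array had MYC changed on its own. Of 78 genes within 0.5 log2 units of IRF7 at 0 h, 1 fell more, but of 39 pDC identity genes 30 fell more. Of 47 interferon-stimulated genes, 0 had a lower log2 fold change than IRF7 at 12 h.

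The 6 arrays of a comparison can be split 3 against 3 in 10 ways, the real one included, too few for a share under 0.05. The real split called 4959, 4287 and 4218 genes at 4, 8 and 12 h against 0 h, 2419 at 8 h against 4 h and 431 at 12 h against 8 h. The highest other split called 0 in each, including the splits that part as many replicate numbers, so 1 of 10, the real one, gave as many genes. For the F test over the 4 times, 1 of 100 splits, the real one, reached the real 6108 genes and the highest other gave 2759. That share is the lowest that 100 splits can give. These splits were drawn without regard to replicate number.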

How the results depend on the processing

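The scalings by probes detected on all 12 arrays and by ribosomal proteins were chosen after the results were seen. Most alternatives left the counts within 1.5 times and the calls in place, but the count at 12 h against 8 h moved under many of them, and the cause was not tested. Signal over background is relative to other probes on an array, so a change shared by all genes cannot be seen. Median scaling put the median log2 fold change of all genes at -0.30, -0.21, 0.17 and 0.41 at 4, 8 and 12 h against 0 h and at 12 h against 8 h. The series matrix values put it at -0.32 at 4 h and 0.22 at 8 h against 4 h, and ribosomal scaling at -0.32, -0.28, 0.34 and -0.30 at 4 h, 12 h, 8 h against 4 h and 12 h against 8 h. The scaling by probes detected on all 12 arrays put it at -0.12 at 12 h and -0.15 at 12 h against 8 h.

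Median scaling called 1404 genes at 8 h against 4 h and 1944 at 12 h against 8 h, and gave IRF7 0.28 there (adjusted p = 0.453). At 12 h against 8 h, 253 genes were called without the filter on dim probes, 780 with replicate as a block, 209 with only the 2 times compared, 730 with array weights, and 660 and 1427 with the added scalings by probes detected on all 12 arrays and by ribosomal proteins. IRF7 at 8 h against 4 h stayed at -0.59 without the filter (adjusted p = 0.0715) and with only the 2 times (adjusted p = 0.0551). Under the added scaling by detected probes IRF7 at 4 h was 0.26 (adjusted p = 0.291). Detection on all 12 arrays called 6 lists at 12 h against 0 h and 8 at 12 h against 4 h, where MYC was not tested and has no value. At least 2-fold, 2176, 1858 and 1834 genes changed at 4, 8 and 12 h, 833 at 8 h against 4 h and 191 at 12 h against 8 h. The ribosomal protein list turned round in 2 settings: 12 h against 4 h with the series matrix values (0.10, but the test pointed lower, adjusted p = 0.858) and 4 h against 0 h with detected probes (0.30 against -0.13, adjusted p = 0.0376).

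With an array or a replicate left out, the counts ran from 3053 to 5100, 2540 to 4434 and 2432 to 4276 at 4, 8 and 12 h, from 916 to 2973 at 8 h against 4 h, from 15 to 910 at 12 h against 8 h and from 3561 to 6272 over the 4 times. MYC ran from -0.14 to 0.21 at 8 h against 4 h and 1.23 to 1.62 at 12 h against 8 h, and IRF7 from -0.86 to -0.61 at 8 h and -0.73 to -0.43 at 8 h against 4 h. Lists called at 12 h against 4 h ran from 9 to 15. Array weights put replicate 2 at 0.43 to 0.61 and the other arrays at 1.07 to 1.72. At 12 h against 8 h the count was lowest without replicate 3 (15) and highest without replicate 2 (910). Leaving out a replicate left 2 arrays at each time, so a call that ended there need not mean a smaller change. Of 6075 other values of single genes over 15 settings, 5897 were the same, 80 weaker, 66 stronger and 32 moved, and of 1468 list values 1351 were the same, 44 weaker, 18 stronger and 53 moved.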

Other observations

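The genes and gene families in this part, and the tests on them, were chosen after the values were seen. BATF, a transcription factor of lymphocyte activation, was at least 20.3-fold, 24.3-fold and 21.6-fold higher at 4, 8 and 12 h than at 0 h (adjusted p = 1.62e-11, 8.29e-12 and 1.37e-11). MIR155HG, the host gene of a microRNA of immune activation, was 24.7-fold, 24.1-fold and 16.5-fold higher (log2 fold changes 4.62, 4.59 and 4.04, SE 0.18, adjusted p of 8.16e-11 or lower), and the cyclin gene CCND2 27.2-fold, 9.31-fold and 12.5-fold. CD69, an early activation receptor, was 39.2-fold higher at 4 h and fell by 1.56 on the log2 scale from 4 to 8 h (adjusted p = 0.00834), while the metallothionein gene MT2A rose by 1.94 over the same interval (adjusted p = 4.81e-05).

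FCER1G, the signalling chain that carries CLEC4C signals, had log2 fold changes of -1.74, -4.46 and -4.38 at 4, 8 and 12 h (adjusted p = 0.000177, 8.89e-09 and 1.32e-08), SYK, the kinase downstream of it, -3.97, -2.64 and -2.45, and the inflammasome adaptor gene PYCARD -2.68, -4.47 and -4.37. SYK rose again between 4 and 8 h (1.33, adjusted p = 0.000833). The interferon receptor gene IFNAR2 had -3.26, -2.75 and -2.44, and IFNAR1 -2.01, -1.10 and -1.07. Among 312 families formed by symbol stem and tested relative to all genes, at 12 h against 4 h 14 of 28 mitochondrial ribosomal genes of the MRPS stem rose and 0 fell (median 0.47; adjusted p = 0.0148, and adjusted p = 0.709 with an estimated correlation), and 20 of 49 of the MRPL stem rose and 2 fell (median 0.37; adjusted p = 0.0142, and adjusted p = 0.709 with an estimated correlation). These were 2 of 16 families called there, 0 of them with an estimated correlation, and among the others 8 of 9 genes of the RNU stem fell (median -1.89; adjusted p = 1.09e-06, and adjusted p = 0.644 with an estimated correlation). Against 0 h the MRPS and MRPL stems were not called at 4 h (adjusted p = 0.952 and 0.858), 8 h (0.419 and 0.15) or 12 h (0.127 and 0.0576). Other scalings were not run on these families.

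MYC and 33 of 51 MYC-activated growth genes were higher at 12 h than at 0 h, with 2 lower (adjusted p = 1.59e-08 for the list, and adjusted p = 0.212 with an estimated correlation), while IRF7 and 34 of 39 pDC identity genes were lower. At 4 h MYC was at least 7.48-fold higher on the probe used (log2 fold change 3.31, adjusted p = 2.46e-09, and 2.11 on a second probe). IRF7 did not pass the test then (-0.14, adjusted p = 0.59). At that time the identity list was already lower (30 of 39 fell, adjusted p = 9.26e-08) and the growth list was not called (median 0.02, adjusted p = 0.189). These arrays do not separate MYC from the other changes that CpG-B brought. An arm without CpG-B at each time, and one with MYC blocked, would separate them.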
